A study of Mus musculus with 6 samples.

How the data were processed

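Gene expression was profiled by Affymetrix microarray in 6 RNA samples from conditionally immortalized mouse podocyte lines, 3 wildtype and 3 with knockout of Nck1 and Nck2, differentiated for 10 days. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cDNA was hybridized. The deposited values are log2 probe set intensities, 1 column per array, made by the authors with the R package affy 1.44.0 and RMA, per the submitters' processing notes. RMA corrects the background of each array, quantile-normalizes over arrays and summarises the probes of a set on the log2 scale. Any filter, the probe definition file and the order of steps are not given in the sources used here, and no scanner files were used, so background correction and summary were taken as the authors left them. The values fit the log2 scale of RMA, with array minima from 1.90 to 2.24, maxima from 13.9 to 14.0 and medians from 6.73 to 6.81. The array medians were not identical, and the SD over genes ran from 1.80 to 1.88. All per-array columns were used. The replicates are described as independent, and no dates or batches were given.

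The median polish of RMA can give arrays the same fitted value, and 12882 genes had at least 1 pair of arrays with identical values. The 3 values of a group were identical for 1648 genes in knockout and 319 in wildtype, 1922 genes in either group and 45 over all arrays. Such genes made up 6.3% of those tested and 1.3% of those called changed. Identical values within a group understate the replicate spread, so leaving out these genes was tried as an alternative.

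The array held 72688 probe sets, of which 186 were controls. Gene names came from the platform annotation, in which 32750 probe sets had a symbol, 31235 named 1 gene after repeats of a symbol were treated as 1 gene, and 1515 named several and were not used by name. The treatment of repeats was decided after the file was seen and before any test. Another 39752 probe sets had no gene entry there, which leaves them unnamed here. Symbols were updated through gene identifiers and synonyms of a reference table of assembly GRCm38.p6, which changed 1196 symbols. That table was used only for names, chromosome membership and order along a chromosome, since the build behind the annotation was not named. For each of 438 genes with several probe sets the one with the highest mean was kept, leaving 30687 genes, of which 30685 were found in the table. Near-identical paralogs can share probes, so values within such families are uncertain.

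No detection calls were used. The 23 background probe sets of the array had means from 2.33 to 7.78 (median 4.48), and 19309 genes (62.9%) had a mean at or below the highest of them. A mean at or below 7.78 is called within the background range. Probes differ in their own background, so this range is wide and a gene within it is not shown to be silent. Of the 119 genes named by rule, 35 had 1 group and 11 had both groups within it, the latter being Nck2, Nphs1, Wt1, Mmp13, Dsp, Ttk, C1s1, Hey1, Mcam, Flt1 and Eif2s3y.

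Knockout was compared with wildtype by limma 3.58.1 in R 4.3.3, with lmFit and eBayes giving a two-sided moderated test per gene, no covariate, no filter on dim genes, and Benjamini-Hochberg adjustment at 0.05. A second count asked in addition for a log2 fold change of at least 1 in size. Gene lists, 36 in number, were fixed before the data were examined, and the 34 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The result of 1 of these lists is not reported here, though it is included in the counts of lists. Each list's count of changed genes was also taken with adjustment over the list alone. Errors are SDs over 3 arrays for means and limma standard errors for log2 fold changes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

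The genes named were chosen by a rule fixed before the data were examined. It took Nck1 and Nck2, the podocyte markers, and the 8 highest and 8 lowest fold changes among genes with an adjusted p under 0.05, no overlap between groups, a mean at or above the median of all genes and an established symbol. It also took up to 4 members with the largest change of each central list and up to 3 of each other list, or the leading 2 where fewer passed. Other genes named were chosen after their values were seen. Of the endothelial list, Flt1 was named by the rule with a log2 difference of 0.12 that did not pass (limma adjusted p = 0.186) except with array weights (adjusted p = 0.00417).

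The scripts were tested on simulated data in which 200 of 30687 genes were changed, drawn at the spread of these arrays. For knockout against wildtype, limma recovered 52.2% of 67 genes changed by 0.5 on the log2 scale, 91.0% of 67 changed by 1 and 100% of 66 changed by 2, with 5 false calls. A shifted list was called and 0 of 33 other lists were. The simulated genes varied independently of each other, so this does not test false list calls from correlated genes. In these arrays the estimated correlation was 0.273 for the oxidative phosphorylation list.

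Alternatives fixed before the data were examined were replicate number as a block, leaving out the dimmest 40% of genes, averaging a gene's probe sets, quantile normalization run again, median centring, eBayes with trend and robust estimation, array weights, leaving out each array, an adjusted p threshold of 0.01, testing all 72502 probe sets that are not controls, limma treat against a fold of 1.2, camera with an estimated correlation, and fry. Leaving out genes with identical values, leaving out genes of X and Y, and taking off chromosome medians were added after the data were seen. The comparison by chromosome used the 9609 brighter protein-coding genes and was likewise added after the data were seen.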

Results

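Gene expression was measured in cultured mouse podocytes, the glomerular epithelial cells whose interdigitating foot processes form the kidney's filtration barrier. The cell lines were conditionally immortalized, so that they grow under a permissive condition and differentiate once it is withdrawn, and total RNA was taken after 10 days of differentiation on type I collagen. A wildtype line and a line with knockout of both Nck1 and Nck2 were each represented by 3 arrays, described as independent replicates of each line, giving 6 arrays. Nck1 and Nck2 are adaptor proteins that link tyrosine-phosphorylated receptors, nephrin among them, to assembly of the actin cytoskeleton. The arrays gave log2 intensities for 30687 genes, with array medians from 6.73 to 6.81. Pearson correlations across genes were 0.993 to 0.997 within a group and 0.978 to 0.985 between groups. Within the wildtype group, arrays 1 and 2 stood farthest apart, with an SD of 0.24 for the log2 difference across genes, against 0.13 to 0.17 for the other pairs within a group. The first principal component separated the genotypes and held 72.6% of the variance, and the next held 14.7% and separated wildtype arrays 1 and 2. The number of arrays limits the precision.

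The first question was whether the targeted transcripts and the podocyte markers differed between the lines. Nck1 (probe set TC0900002936.mm.1, chromosome 9) fell from 8.63 ± 0.10 in wildtype to 8.12 ± 0.06 in knockout (mean log2 intensity ± SD, n = 3 each), a log2 fold change of -0.51 with a standard error of 0.07 and a limma adjusted p of 0.00391 after Benjamini-Hochberg adjustment. Nck2 (probe set TC0100000323.mm.1, chromosome 1) was at 7.48 ± 0.13 and 7.24 ± 0.04, a log2 difference of -0.24 that did not pass over all genes (limma adjusted p = 0.0942; -0.16 with chromosome medians taken off, an alternative added after the data were seen, and passing with array weights at adjusted p = 0.00271), with all 3 knockout values below all 3 wildtype values. Adjusted over the list alone, both targeted genes passed. The fit with array weights stopped before converging and gave wildtype array 3 a weight of 54.98. A pass under that fit alone, here or elsewhere, is therefore not relied on. Both Nck2 means lay within the range of the array's background probe sets, and the position of either probe set relative to the deleted part of its gene is not known, so these values check the genotype labels only weakly. The podocyte markers did not pass: Nphs1, which encodes nephrin, differed by -0.02 (95% confidence interval -0.17 to 0.13), the transcription factor gene Wt1 by -0.04 (-0.15 to 0.06), the actin-associated Synpo by 0.02 (-0.09 to 0.12) and the surface sialomucin gene Podxl by 0.09 (-0.08 to 0.26), with limma adjusted p from 0.593 to 0.947. Across the alternatives Nphs1 ran from -0.06 to 0.04, Wt1 from -0.06 to -0.004, Synpo from 0.004 to 0.17 and Podxl from 0.04 to 0.18, and Podxl passed with array weights only (0.11, adjusted p = 0.0408). Nphs1 and Wt1 were within the background range in both lines.

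The second question was which genes changed across the genome. Among genes with an established symbol and a mean at or above the median of all genes, the largest rises were in Vip, which encodes vasoactive intestinal peptide, from 6.30 ± 0.35 to 11.58 ± 0.06, and in the stromelysin gene Mmp10, from 6.28 ± 0.05 to 11.01 ± 0.11, log2 fold changes of 5.28 (SE 0.17) and 4.73 (SE 0.07). The Y-linked Uty rose by 4.69, the vasodilator peptide gene Adm by 4.50, the collagen-binding proteoglycan gene Dcn by 4.33, the growth factor gene Pdgfd by 4.20, the receptor phosphatase gene Ptprb by 4.11 and the prostaglandin E receptor gene Ptger3 by 4.11. The largest falls in that set were in Xist, the noncoding RNA that silences the inactive X chromosome, from 12.19 ± 0.04 to 6.01 ± 0.05, and in Postn, which encodes the matrix protein periostin, from 12.36 ± 0.10 to 6.39 ± 0.05, log2 fold changes of -6.18 (SE 0.05) and -5.97 (SE 0.07). Ctsc, encoding the lysosomal protease cathepsin C, changed by -4.38, the water channel gene Aqp1 by -3.50, the anoctamin gene Ano3 by -3.49, the glutamate receptor gene Gria3 by -3.29, the epithelial integrin gene Itgb6 by -3.09 and the antisense transcript Slc13a2os by -3.09. These 16 genes had limma adjusted p values from 1.68e-07 to 3.52e-05. The rule that chose them required an adjusted p under 0.05 and no overlap between the 3 values of each line. The wildtype means of all 8 risen genes lay within the background range, as did the knockout means of Xist, Postn, Ctsc, Ano3 and Itgb6 among the fallen genes, so these fold changes depend on a level that was not separated from background.

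Of the 30687 genes tested, 3667 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 1549 higher and 2118 lower in knockout, and 515 of them changed at least 2-fold, 287 higher and 228 lower. At an unadjusted p under 0.05 there were 7087 genes. The 2 groups did not overlap for 8402 genes, 27.4% of those tested, where chance gives 10%. Of 19217 protein-coding genes, 3081 changed. Of the 515 genes, 298 had their lower group within the background range and 65 had both. The count of changed genes was 2078 without wildtype replicate 3, 2231 without knockout replicate 1 and 2309 without knockout replicate 2; array weights gave 10164, and a threshold of 0.01 gave 1947. With chromosome medians taken off the split was 2730 higher and 1690 lower. Those medians came from the brighter protein-coding genes but were taken off all genes of a chromosome. The median log2 fold change over all genes moved from 0.012 to 0.053, so part of that split can come from the offset itself.

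**Figure D1:**
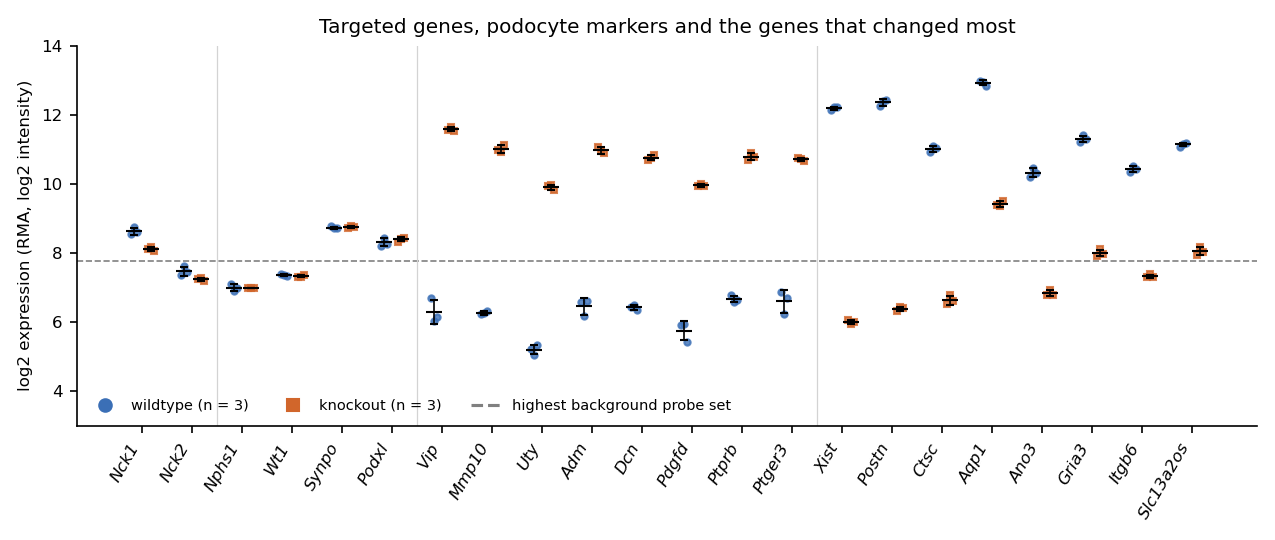
Log2 RMA intensity of the targeted genes, podocyte markers and the 16 genes with the largest changes, among those with an established symbol and a mean at or above the median of all genes, in each of 3 wildtype arrays (blue circles) and 3 knockout arrays (orange squares), with horizontal bars at group means, error bars of 1 SD, and a dashed line at 7.78, the mean of the brightest background probe set. The podocyte markers overlap or nearly overlap between lines, while those 16 genes differ by log2 fold changes that run from -6.18 to 5.28.

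Contractile genes were higher in knockout. Acta2, the smooth muscle actin gene, rose from 10.07 ± 0.19 to 12.90 ± 0.07, a log2 fold change of 2.83 (SE 0.10, limma adjusted p = 2.35e-05), and of the smooth muscle cytoskeletal genes Tagln rose by 2.70 (SE 0.17), Myl9 by 2.01 (SE 0.12) and Cnn1 from 8.11 ± 0.12 to 9.31 ± 0.06. Of 22 measured targets of the serum response factor and its actin-regulated cofactors, 15 rose, 1 fell and 6 did not pass, and 17 passed adjusted over the list alone. The one that fell was the immediate early gene Egr1 (-0.27, chosen after its value was seen). The list median was 0.44, and the list moved up relative to other genes (camera adjusted p = 7.03e-11, and adjusted p = 0.0539 with an estimated correlation). Beside these genes, the pericyte receptor gene Pdgfrb rose from 7.56 ± 0.10 to 9.92 ± 0.13 (log2 fold change 2.36, SE 0.08), the wildtype mean being within the background range.

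Targets of the YAP and TEAD transcription factors and of TGF-beta signalling also moved. These lists share 2 genes, Ccn2 and Tgfb2. The YAP and TEAD list also shares 2 genes with the serum response factor list. The TGF-beta list shares 3 with the fibrillar and interstitial matrix list described below. The shifts of these lists are thus not independent of each other. Of 23 YAP and TEAD targets 10 rose, 2 fell and 11 did not pass, 16 passed adjusted over the list alone, and the median was 0.27 (camera adjusted p = 0.000132, and adjusted p = 0.237 with an estimated correlation). The matricellular gene Ccn2 rose by 1.31 (SE 0.08), the growth factor gene Tgfb2 by 1.23 (SE 0.11) and the RNA-binding protein gene Rbms3 by 1.11 (SE 0.06), and Nt5e, encoding the ectonucleotidase CD73, changed by -1.68 (SE 0.11). The other gene that fell was the kinase gene Nuak2 (-0.86, chosen after its value was seen). Of 20 TGF-beta targets 10 rose, 3 fell and 7 did not pass, 13 passed adjusted over the list alone, and the median was 0.23 (camera adjusted p = 0.00134, and adjusted p = 0.156 with an estimated correlation). Tgfbi, encoding a secreted matrix protein, rose by 1.51 (SE 0.11). The wildtype means of Rbms3 and Tgfbi lay within the background range. Those that fell were Id2 (-0.76), Fn1 (-0.57) and Ltbp3 (-0.41), chosen after their values were seen.

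Extracellular matrix genes changed by large amounts in both directions. Col1a1, a chain of type I collagen, rose from 8.54 ± 0.12 to 11.56 ± 0.09, a log2 fold change of 3.03 (SE 0.08, limma adjusted p = 1.08e-05), the fibrillar collagen gene Col5a2 rose by 3.79 (SE 0.09) and the fibulin gene Fbln2 by 3.08 (SE 0.05). Of 28 fibrillar and interstitial matrix genes 15 rose, 3 fell and 10 did not pass, 19 passed adjusted over the list alone, and the median was 0.38 (camera adjusted p = 3.48e-08, and adjusted p = 0.156 with an estimated correlation). Beside Postn, those that fell were the collagen crosslinking enzyme gene Lox (-2.42) and the fibronectin gene Fn1 (-0.57), chosen after their values were seen. The wildtype mean of Col5a2 and the knockout mean of Lox lay within the background range. Of 24 matrix proteases and inhibitors 13 rose, 1 fell and 10 did not pass, 18 passed adjusted over the list alone, and the median was 0.25 (camera adjusted p = 6.49e-05, and adjusted p = 0.191 with an estimated correlation). The aggrecanase gene Adamts5 rose by 1.42 (SE 0.07) and the collagenase gene Mmp13 by 1.31 (SE 0.07) with both means within the background range, and the gelatinase gene Mmp2 changed by -1.01 (SE 0.06).

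The basement membrane genes went both ways. Of 20 measured, 6 rose, 6 fell and 8 did not pass, and 13 passed adjusted over the list alone. Col4a2 and Col4a1, which encode the widely expressed chains of type IV collagen, rose by 2.56 (SE 0.08) and 2.19 (SE 0.09), and the laminin-binding Nid1 rose by 2.18 (SE 0.11). Lama1, a laminin chain of early basement membranes, changed by -1.48 (SE 0.07). The lower mean of Nid1 and of Lama1 lay within the background range. The X-linked pair Col4a5 and Col4a6, which were chosen after their values were seen, changed by -0.98 and -1.02. The list did not shift by camera (adjusted p = 0.944), and its median of -0.01 and mean of 0.17 differed in sign.

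Slit diaphragm genes moved up as a list by camera, and most podocyte identity genes did not pass. Of 13 slit diaphragm and junction genes 4 rose, none fell and 9 did not pass, 4 passed adjusted over the list alone, and the median was 0.08 (camera adjusted p = 0.00203, and adjusted p = 0.191 with an estimated correlation). Those that rose were Plce1, a phospholipase C gene mutated in inherited nephrotic syndrome, by 3.12 (SE 0.05) from a background-range wildtype mean, the motor gene Myo1e by 0.84 (SE 0.06), the protocadherin gene Fat1 by 0.53 (SE 0.05) and the kinase gene Fyn by 0.49 (SE 0.06). Of 24 podocyte identity genes 3 rose, 2 fell and 19 did not pass, with 5 adjusted over the list alone, and the list did not shift by camera (adjusted p = 0.322), while fry called it up (adjusted p = 0.029). Podoplanin, Pdpn, rose by 3.64 (SE 0.12) from a background-range wildtype mean, the actin crosslinker gene Actn4 by 0.61 (SE 0.04) and, chosen after its value was seen, Vegfa by 0.55, while the transcription factor gene Foxc1 changed by -1.14 (SE 0.09) and Thsd7a, a podocyte membrane antigen gene, by -1.09 (SE 0.09). Of these 24 genes, 12 had both means within the background range.

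Adhesion genes and partners of Nck moved in both directions. Of 32 integrin and focal adhesion genes 8 rose, 7 fell and 17 did not pass, and 18 passed adjusted over the list alone. Beside Itgb6, the integrin gene Itga9 changed by -0.97 (SE 0.07) and the tensin gene Tns3 by -0.94 (SE 0.05), while Lims2, of the integrin-linked kinase complex, rose by 0.92 (SE 0.06). Of 35 Nck partners and actin nucleation genes 3 rose, 5 fell and 27 did not pass, and 18 passed adjusted over the list alone. The WAVE complex genes Wasf3 and Abi2 changed by -1.41 (SE 0.07) and -0.51 (SE 0.06), and the Rac exchange factor gene Dock1 by -0.51 (SE 0.06). The lower means of Itga9, Lims2 and Wasf3 lay within the background range. The ubiquitin ligase gene Cbl rose by 0.41 (SE 0.08, limma adjusted p = 0.02), a call lost without wildtype replicate 3 or any knockout replicate (adjusted p from 0.0571 to 0.0834). Neither list shifted by camera, at adjusted p = 0.432 for adhesion and 0.231 for Nck partners, and the latter passed without wildtype replicate 1 (adjusted p = 0.029, where the alternatives run from 0.029 to 0.868) and was called down by fry (adjusted p = 0.0433).

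Oxidative phosphorylation genes were lower in knockout. Of 25 measured subunits of the respiratory chain and ATP synthase 19 fell, 1 rose and 5 did not pass, and 23 passed adjusted over the list alone. The median was -0.51, and the list moved down relative to other genes (camera adjusted p = 2.03e-15, and adjusted p = 0.156 with an estimated correlation). The complex I genes Ndufb8 and Ndufa1 fell from 8.88 ± 0.12 to 8.10 ± 0.06 and from 9.35 ± 0.08 to 8.58 ± 0.09, each a log2 fold change of -0.78 (SE 0.07), and the cytochrome c oxidase gene Cox5b changed by -0.77 (SE 0.09). The gene that rose was Ndufb3 (0.42, chosen after its value was seen). Of 14 tubular markers, 6 fell beside this list, among them Aqp1 (-3.50), Cdh16 (-1.50), Pax8 (-0.73) and Lrp2 (-0.36), and 8 did not pass, among them Aqp2 (0.03, chosen after its value was seen), with a median of -0.002. Of 23 hypoxia and glycolysis genes 10 rose, 2 fell and 11 did not pass, 15 passed adjusted over the list alone, and the median was 0.18 (camera adjusted p = 0.000198, and adjusted p = 0.263 with an estimated correlation). Beside Adm, the hypoxia-responsive Ndrg1 rose by 1.06 (SE 0.08) and the lactate dehydrogenase gene Ldha by 0.85 (SE 0.06). Those that fell were the glycolytic enzyme genes Pfkp (-0.49) and Pgk1 (-0.27), chosen after their values were seen.

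Some cholesterol synthesis genes were higher in knockout. Of 19 measured 10 rose, none fell and 9 did not pass, with 10 adjusted over the list alone, and the median was 0.32 (camera adjusted p = 5.22e-07, and adjusted p = 0.156 with an estimated correlation). The squalene-forming and squalene-oxidizing enzyme genes Fdft1 and Sqle rose by 0.89 (SE 0.07) and 0.99 (SE 0.07), and the lanosterol demethylase gene Cyp51 by 0.77 (SE 0.09). Oxidative stress genes went apart. The metallothionein genes Mt2 and Mt1 rose by 2.92 (SE 0.19) and 2.72 (SE 0.11) and the heme oxygenase gene Hmox1 by 1.62 (SE 0.11), while 8 of the 17 measured genes fell and 6 did not pass. The list passed for 15 genes adjusted over the list alone and missed the threshold as a set (camera adjusted p = 0.0542), which it passed without wildtype replicate 1 (adjusted p = 0.0188) or knockout replicate 3 (adjusted p = 0.011, where the alternatives run from 0.011 to 0.522). Camera also called it down with the replicate block (adjusted p = 0.0318), array weights (0.0475) and chromosome medians taken off (0.0123), but not with an estimated correlation (0.522). By fry it was called down (adjusted p = 0.0156). Of 18 unfolded protein response genes 0 passed in limma, over all genes or over the list alone, and 3 had an unadjusted p under 0.05; the largest differences were 0.26 for Trib3 and 0.23 for Atf4, at limma adjusted p = 0.102 and 0.0532, and fry did not call the list (adjusted p = 0.602). Atf4 passed with the dimmest 40% of genes left out (adjusted p = 0.0311) and with quantile normalization run again (adjusted p = 0.0332), Trib3, whose wildtype mean is within the background range, passed without wildtype replicate 1 (0.33, adjusted p = 0.0486), and both passed with array weights (adjusted p = 0.00276 and 0.00206). With chromosome medians taken off Atf4 was at 0.12. Of 21 lysosome and autophagy genes 2 rose and 6 fell, with 9 adjusted over the list alone. The hexosaminidase gene Hexa rose by 0.88 (SE 0.08) and the cathepsin gene Ctsb by 0.75 (SE 0.07), and the cholesterol transporter gene Npc1 changed by -0.48 (SE 0.07).

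**Figure D2:**
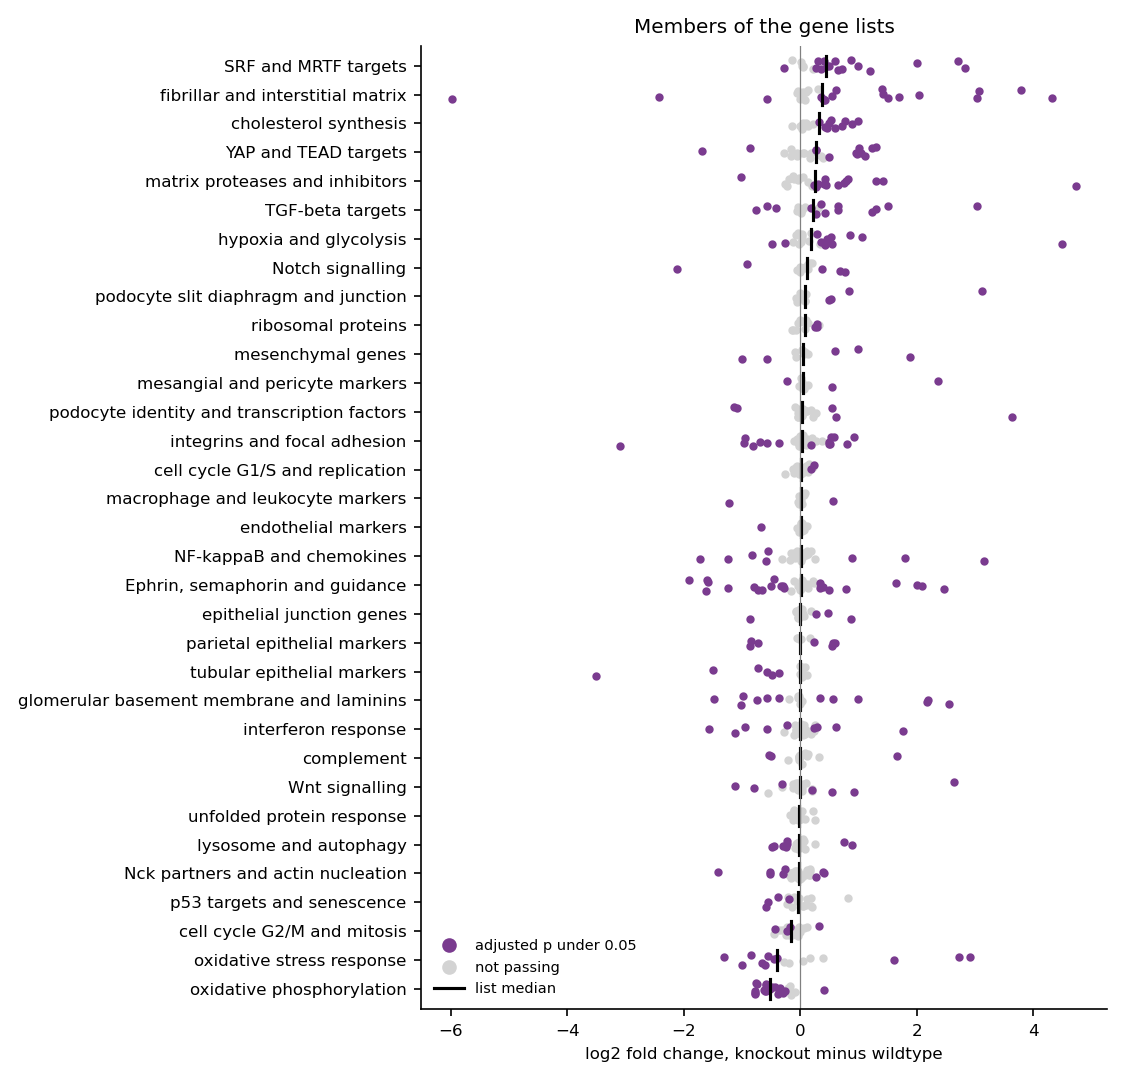
Log2 fold change, knockout minus wildtype, of every measured member of the gene lists tested and reported here, 1 list per row, with members of limma adjusted p under 0.05 in purple, other members in grey and the list median as a black bar. The medians run from -0.51 for oxidative phosphorylation to 0.44 for targets of the serum response factor, and most rows hold members on both sides of 0.

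Guidance and signalling genes changed in both directions. Of 34 ephrin, semaphorin and guidance genes 9 rose, 13 fell and 12 did not pass, and 24 passed adjusted over the list alone. The secreted guidance cue genes Sema3d, Slit2 and Sema3a rose by 2.47 (SE 0.08), 2.10 (SE 0.08) and 2.00 (SE 0.06). Of 14 Notch genes 3 rose and 2 fell, with 7 adjusted over the list alone. The ligand gene Jag1 fell from 11.59 ± 0.05 to 9.48 ± 0.11 (log2 fold change -2.12, SE 0.07), the Notch glycosyltransferase gene Lfng changed by -0.91 (SE 0.07), and the target gene Hey1 rose by 0.76 (SE 0.06). Chosen after their values were seen, Hey2 rose by 0.69 and Rbpj by 0.37, and both means of Hey1 and of Hey2 lay within the background range. Of 25 Wnt genes 4 rose and 3 fell, with 9 adjusted over the list alone. The Wnt modulator gene Dkk2 rose by 2.64 (SE 0.17), Dkk3 changed by -1.12 (SE 0.07) and the transcription factor gene Lef1 rose by 0.93 (SE 0.08). The wildtype means of Sema3d, Slit2, Dkk2 and Lef1 lay within the background range. None of these lists shifted by camera, while fry called the guidance list down (adjusted p = 0.0433).

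Inflammatory genes also went both ways. Of 27 NF-kappaB and chemokine genes 3 rose and 5 fell, with 10 adjusted over the list alone. Ptgs2, encoding the inducible cyclooxygenase, rose from 9.38 ± 0.13 to 12.53 ± 0.10 (log2 fold change 3.15, SE 0.08) and the chemokine gene Cxcl12 by 1.81 (SE 0.20), while the chemokine gene Ccl2 changed by -1.71 (SE 0.10). Of 32 interferon response genes 4 rose and 5 fell, with 10 adjusted over the list alone. The tetherin gene Bst2 rose by 1.77 (SE 0.20), and the interferon-induced Ifit3 and Gbp2 changed by -1.57 (SE 0.08) and -1.13 (SE 0.08). Of 17 complement genes 1 rose and 2 fell, with 4 adjusted over the list alone. They were C2 (1.66, SE 0.12, and 0.82 with its probe sets averaged), C1rl (-0.50, SE 0.06) and C1s1 (-0.54, SE 0.10), the last with both means within the background range and its call lost without wildtype replicate 3 or any knockout replicate (adjusted p from 0.0529 to 0.0812). The wildtype means of Cxcl12 and C2 lay within the background range. None of these lists shifted by camera.

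Proliferation genes changed little. Of 24 genes of mitosis 1 rose, 3 fell and 20 did not pass, with 5 adjusted over the list alone and a median of -0.16. The list moved down (camera adjusted p = 0.00265, and adjusted p = 0.658 with an estimated correlation), a call lost without wildtype replicate 2 (adjusted p = 0.118, where the alternatives run from 6.81e-06 to 0.658). Topoisomerase gene Top2a changed by -0.43 (SE 0.10), the kinase genes Aurkb by -0.22 (SE 0.05) and Ttk by 0.33 (SE 0.08), with limma adjusted p from 0.0459 to 0.0495, and the centromere gene Cenpa, chosen after its value was seen, by -0.17. Both means of Ttk and the knockout means of Aurkb and Cenpa lay within the background range. Of 23 genes of DNA replication the helicase subunit genes Mcm2 and Mcm5 rose by 0.23 (SE 0.04) and 0.19 (SE 0.04), 0 fell, 2 passed adjusted over the list alone, and the list did not shift. Each of these calls was lost without wildtype replicate 3, without knockout replicate 1 and without knockout replicate 2 in limma, with adjusted p of 0.173, 0.0966 and 0.0719 for Top2a, 0.157, 0.161 and 0.151 for Aurkb, 0.127, 0.119 and 0.158 for Ttk, 0.0878, 0.0757 and 0.0727 for Mcm2, and 0.133, 0.11 and 0.109 for Mcm5. Top2a also lost its call without each other replicate, Aurkb without wildtype replicate 1 or 2, and Ttk, Mcm2 and Mcm5 without knockout replicate 3 (adjusted p from 0.0524 to 0.145). The replicate block ended the calls of Top2a, Aurkb, Mcm2 and Mcm5 (adjusted p from 0.0525 to 0.0955). With chromosome medians taken off, which shrinks the folds and leaves their SE as they were, Top2a was at -0.31, Aurkb at -0.10 and Ttk at 0.31, and none passed (limma adjusted p = 0.107, 0.289 and 0.0548). Of 19 p53 targets 4 fell and 15 did not pass, with 5 adjusted over the list alone and no shift by camera. The membrane protein gene Perp changed by -0.59 (SE 0.06), the receptor gene Eda2r by -0.55 (SE 0.09), the kinase gene Plk2 by -0.38 (SE 0.07) and, chosen after its value was seen, Phlda3 by -0.18. The X-linked Eda2r missed the threshold without wildtype replicate 3 (adjusted p = 0.0516) and, at -0.30, with chromosome medians taken off (adjusted p = 0.0708), and Plk2 without any wildtype replicate or knockout replicate 2 (adjusted p from 0.0508 to 0.0776).

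Markers of other cell types were read beside these groups. Of 14 tubular epithelial markers 6 fell and 8 did not pass, with 6 adjusted over the list alone, and the list moved down (camera adjusted p = 0.00285, and adjusted p = 0.33 with an estimated correlation), although its median was -0.002 and its mean -0.49. Beside Aqp1, the kidney cadherin gene Cdh16 changed by -1.50 (SE 0.11) and the transcription factor gene Pax8 by -0.73 (SE 0.06), and, chosen after their values were seen, the endocytic receptor genes Cubn by -0.56 and Lrp2 by -0.36 and the injury marker gene Havcr1 by -0.48, where both means of Cubn and of Havcr1 were within the background range. Of 12 parietal epithelial markers 4 rose and 3 fell, with 7 adjusted over the list alone, among them the scaffold gene Akap12 at -0.85 (SE 0.08) and the tight junction gene Cldn1 at -0.87 (SE 0.05). Of 10 mesangial and pericyte markers Pdgfrb and Sfrp2 rose, the latter by 0.55 (SE 0.06), and the adhesion molecule gene Mcam changed by -0.22 (SE 0.04), with 3 adjusted over the list alone, and both Mcam means and the wildtype mean of Sfrp2 were within the background range. Camera did not call that list, and fry called it up (adjusted p = 0.029). Of 13 endothelial markers Ehd3 changed by -0.67 (SE 0.09), 12 did not pass, and 1 passed adjusted over the list alone. Of 11 macrophage and leukocyte markers Csf1r, the receptor of a macrophage growth factor, changed by -1.21 (SE 0.08) and the lysosomal Cd68 rose by 0.57 (SE 0.14, limma adjusted p = 0.0471), with 2 adjusted over the list alone. The Mcam call was lost without wildtype replicate 3, without any knockout replicate and with the replicate block (adjusted p from 0.0533 to 0.088), and that of Cd68 without any wildtype replicate, knockout replicate 1 or knockout replicate 2 (adjusted p from 0.0515 to 0.173).

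Epithelial, mesenchymal and ribosomal genes did not shift as lists by camera, while fry called the mesenchymal list up (adjusted p = 0.016). Of 22 epithelial junction genes 3 rose and 1 fell, with 4 adjusted over the list alone and 18 in the background range in both lines. The desmosome gene Dsp rose by 0.87 (SE 0.12) with both means in that range, the tight junction gene F11r by 0.47 (SE 0.06) and, chosen after its value was seen, the plakoglobin gene Jup by 0.27. Of 12 mesenchymal genes 3 rose and 2 fell, with 6 adjusted over the list alone. The homeobox gene Prrx1 rose by 1.89 (SE 0.10) from a background-range wildtype mean, the calcium-binding S100a4 by 1.00 (SE 0.10) and Cd44 by 0.60, while the transcription factor gene Twist2 fell from 9.47 ± 0.08 to 8.46 ± 0.06 and the cadherin gene Cdh2 changed by -0.56, where Cd44 and Cdh2 were chosen after their values were seen. Of 14 ribosomal protein genes Rpl8 rose by 0.29 (SE 0.04, and by 0.18 with chromosome medians taken off), Rps9 by 0.29 (SE 0.05) and Rpl4 by 0.26 (SE 0.05), with 3 adjusted over the list alone and camera adjusted p = 0.108 for the list, which passed without wildtype replicate 2 (adjusted p = 0.0279, where the alternatives run from 0.0279 to 0.796). Camera also called the ribosomal list up with chromosome medians taken off (adjusted p = 0.0365). Rps9 lost its call without wildtype replicate 3 or any knockout replicate (adjusted p from 0.0548 to 0.0725), and Rpl4 without knockout replicate 1 or 2 (adjusted p = 0.0574 and 0.0613).

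The lines also differed in sex-linked genes. Beside Xist and Uty, the Y-linked demethylase gene Kdm5d rose from 6.12 ± 0.22 to 8.96 ± 0.06 (log2 fold change 2.84, SE 0.11, limma adjusted p = 4.04e-05), the wildtype mean being within the background range, and the Y-linked Eif2s3y was at 4.49 and 4.50, at background in both lines. Of the 4 sex-linked genes measured, 3 passed adjusted over the list alone. Among the brighter protein-coding genes, a set chosen after the data were seen, the 259 genes of the X chromosome had a median log2 fold change of -0.25, with 81.9% of them lower and, by limma, 99 fallen and 16 risen. The median over all 9609 such genes was -0.03. Medians also lay below those of all 10000 random gene sets matched on expression for chromosomes 18 (-0.15), 16 (-0.15) and 11 (-0.13), and above them for chromosomes 15 (0.11) and 14 (0.07), among 14 of 20 chromosomes outside the random range. The random sets do not carry the spread between arrays. Medians of the wildtype arrays spanned 0.15 on the X chromosome, 0.101 on chromosome 14, 0.103 on 16 and 0.117 on 18. They spanned 0.065 on 11 and 0.041 on 15. On each of these chromosomes the array medians of the lines did not overlap.

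**Figure D3:**
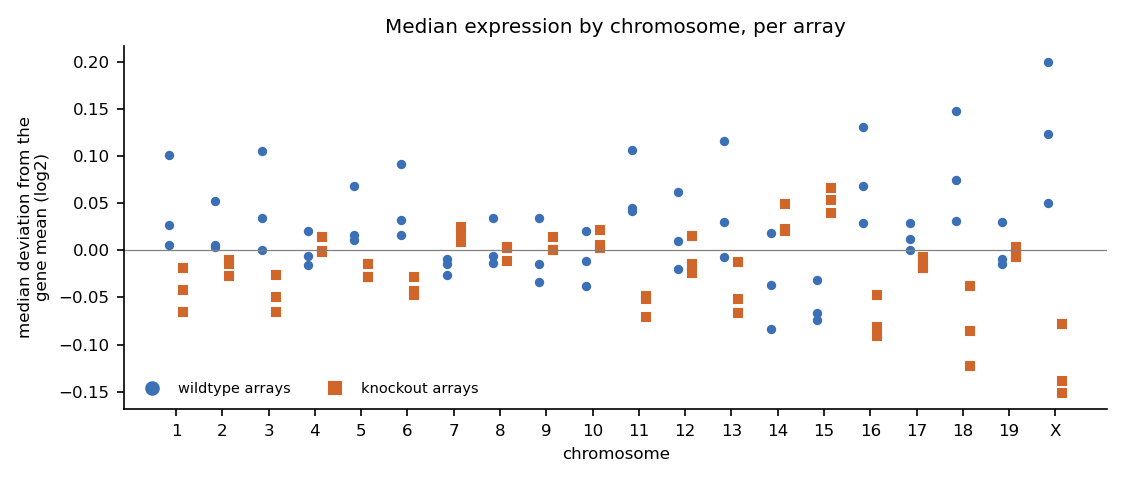
Median deviation of the brighter protein-coding genes of each chromosome from their mean over the 6 arrays, in log2 units, for 3 wildtype arrays (blue circles) and 3 knockout arrays (orange squares). On the X chromosome the wildtype arrays lie at 0.05 to 0.20 and the knockout arrays at -0.15 to -0.08.

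Of 34 lists tested with a preset correlation of 0.01, camera called 12 shifted, 9 up and 3 down, at a Benjamini-Hochberg adjusted p under 0.05. With an estimated correlation camera called 0, with 8 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0539, and fry, which tests whether a list's genes move on balance in one direction, called 18. Its test of change in either direction called all 34. The median, the mean and the direction of the camera test did not share a sign for the lists of basement membrane, adhesion, guidance, NF-kappaB, complement, oxidative stress, Wnt, Notch, parietal, endothelial and macrophage genes, none of them called by camera. Other divisions of the 6 arrays into 3 and 3 gave up to 14 lists by the preset correlation. Each of them mixes the genotypes unevenly and so keeps part of the genotype difference. These counts therefore cannot show whether the number of shifted lists sets the genotypes apart. Each genotype appears to be represented by 1 line, so genotype and line cannot be told apart, and the p-values measure the spread between replicate cultures of these lines.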

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

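The comparison of probe sets without a gene entry was planned as a separate test of every probe set, and the split of its result by naming was chosen after the result was seen.

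Probe sets that carry no gene name here lie outside the gene-level comparison. Of 39752 such probe sets, 1994 (5.02%) changed between the lines in limma over all probe sets (Benjamini-Hochberg adjusted p under 0.05), and 645 (1.62%) changed at least 2-fold, 389 higher and 256 lower in knockout. Of the 32750 probe sets with a gene entry, 2932 (8.95%) changed and 536 (1.64%) changed at least 2-fold. The largest rises were in probe set TC0Y00000235.mm.1, from 5.67 ± 0.07 to 10.67 ± 0.30 (limma adjusted p = 6.48e-05), and TC1300001343.mm.1, from 4.71 ± 0.09 to 9.67 ± 0.11 (log2 fold change 4.96, adjusted p = 1.31e-05). The largest falls were in TC0900000294.mm.1, from 8.87 ± 0.30 to 4.57 ± 0.22 (-4.30, adjusted p = 0.000157), and TSUnmapped00000030.mm.1, from 12.13 ± 0.08 to 8.10 ± 0.24 (-4.03, adjusted p = 6.6e-05). The lower means of the first 3 of these lay within the background range. Probe set TC0Y00000235.mm.1 carries a Y chromosome prefix, as the probe set of Uty does. Among probe sets with a named gene, such prefixes matched the chromosome of the gene for 30521 of 30580 compared. No explanation was tested for the probe sets without a gene entry. Groups of 3 are too small for a test of single outlying arrays.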

How the results depend on the processing

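Leaving out genes with identical values, leaving out X and Y genes and taking off chromosome medians were chosen after the data were seen. Of 119 named genes, 110 passed with the settings of the report, 97 passed under every alternative that gives them a value, 15 or 16 for each. None of the 110 changed direction, while Nphs1 and Eif2s3y, both near 0, changed sign under some alternatives without passing. Whether the replicate numbers pair the samples across lines was not settled. Correlations of same-numbered deviations were 0.35, 0.28 and 0.04, and 5 of 6 arrays correlated best with their own number across lines. The crossed pairs of replicates 1 and 2 were at -0.25 and -0.345. The replicate block gave 3762 changed genes, 3195 of them shared with the report's, 516 at 2-fold and 13 lists, the list added being oxidative stress (camera adjusted p = 0.0318). Array weights gave 10164 changed genes. That fit stopped before converging and gave wildtype array 3 a weight of 54.98 against 0.165 to 1.12 for the others, and wildtype array 3 lay between the other wildtype arrays for 60.8% of genes. An adjusted p threshold of 0.01 gave 1947 genes by its construction. Leaving out 1 array gave 2078 to 3387 changed genes, lowest without wildtype replicate 3, with 484 to 555 at 2-fold and 12 to 14 lists, in fits with fewer arrays. Testing all probe sets gave 1181 at 2-fold, from 72502 tested, and limma treat against a fold of 1.2 gave 1211, a smaller size being asked for. Camera with an estimated correlation called 0 lists, with 8 at an unadjusted p under 0.05, and fry called 18. The basement membrane list turned from down, not passing, in camera to up in fry (adjusted p = 0.0433, where its alternatives run from 0.0433 to 0.999), and the cause was not tested. Nck2 passed with array weights (adjusted p = 0.00271, where its alternatives run from 0.00271 to 0.243). Taking off chromosome medians gave 4420 genes, 498 at 2-fold and 14 lists. The dim signal limits the folds, since 298 of 515 genes at 2-fold had a group within the background range.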

Other observations

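The single genes outside the naming rule, the chromosome, Hox, imprinted gene and cell-type comparisons and the tests of chromosome medians and stretches of X were chosen after the results were seen. The tests against random lists matched on expression, the regression on the difference between wildtype arrays, and the other divisions of the arrays were set before theirs.

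Homeobox genes of the Hoxc cluster, which help set position along the body axis, stood apart from the other clusters. All 9 measured Hoxc genes rose in knockout (limma, Benjamini-Hochberg adjusted p under 0.05), with a median log2 fold change of 1.03 and a range from 0.64 to 3.56, the highest being Hoxc10 (5.18 ± 0.17 to 8.74 ± 0.18, n = 3 each), and the wildtype means of Hoxc10 and most of the others lay within the background range. Of 8 Hoxa genes 0 rose and 1 fell, with 2 at an unadjusted p under 0.05, of 9 Hoxb genes 0 rose and 3 fell, with 5, and of 7 Hoxd genes 0 changed, with 0. Of single imprinted genes on chromosome 7, Peg3 rose by 2.64 (SE 0.06) and Usp29 by 2.05 (SE 0.09), both expressed from the paternal copy, and Zim1, expressed from the maternal copy, by 3.48 (SE 0.12), with wildtype Usp29 and Zim1 within the background range. Imprinted genes as a group were not analysed here.

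Several single genes outside the lists also differed by large amounts. Casp1, encoding the protease of the inflammasome, rose from 4.83 ± 0.13 to 9.36 ± 0.25, a log2 fold change of 4.53 (SE 0.14, limma adjusted p = 1.52e-05) from a background-range wildtype mean. Mme, encoding the membrane protease neprilysin that podocytes and proximal tubules carry, fell from 12.35 ± 0.08 to 9.35 ± 0.09, a log2 fold change of -3.00 (SE 0.07, limma adjusted p = 6.11e-06). Ppargc1a, a coactivator of mitochondrial gene expression, fell from 11.31 ± 0.07 to 9.79 ± 0.13, a log2 fold change of -1.53 (SE 0.08, limma adjusted p = 0.000121). Among the oxidative stress genes that fell while the metallothioneins rose was Gclc, encoding the catalytic subunit for glutathione synthesis, at -1.30 (SE 0.04).

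The lower level of oxidative phosphorylation genes was weighed against 3 accounts. The list median of -0.51 lay below that of every one of 10000 random lists matched on expression, whose lowest was -0.26, which argues against a fall of bright genes as a class. After chromosome medians were taken off it was -0.44, which argues against chromosome-wide shifts as the whole cause. Tubular cells are rich in mitochondria, and of 5 tubular markers above the background range in wildtype 4 fell with the list, so tubular cells in the wildtype cultures cannot be told apart from lower mitochondrial gene expression in knockout podocytes, Aqp2 being the marker that did not pass. A difference in array quality that runs with genotype, and a difference between lines apart from loss of Nck, have no test here.

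The fall across the X chromosome, beside the loss of Xist signal and the gain of Uty and Kdm5d, was weighed next. The X median of -0.25 lay below all 10000 matched random sets (lowest -0.083), which argues against chance placement of genes. Those sets do not carry the spread between arrays, and 14 of 20 chromosomes lay outside their range. The medians of the wildtype arrays alone spanned 0.15 on X. The highest median of 5 stretches of neighbouring X genes was -0.21, which argues against a few genes or 1 region. The lines also differ along the axis between wildtype arrays 1 and 2 (slope -0.64). Regression on that difference left -0.17, below the lowest random set of -0.08. The axis was read from 1 difference between 2 arrays that also enter the fold changes. Noise in it can leave a remainder, so how much of the X fall it accounts for cannot be told. Lines of different sex could give the opposite signals of Xist and of the Y-linked Uty and Kdm5d. The Y-linked Eif2s3y did not share that signal, being within the background range in both lines, and whether its probe set responds was not tested. Loss of a sex chromosome in culture would not by itself give Xist to wildtype (12.19) and Uty to knockout (9.90). These values argue against such a loss as the whole cause. Whether either account would lower genes along the whole X was not tested. Shifts of other chromosomes could come from gains or losses in culture, but DNA copy number was not analysed here. Effects of sex on other chromosomes stay open.

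The rise of contractile genes with the fall of Aqp1 was weighed against other cells. Of 5 tubular markers above the background range in wildtype, 4 (Lrp2, Aqp1, Cdh16 and Pax8) fell and Aqp2 did not pass (0.03), so tubular cells or a tubular state in the wildtype line cannot be told apart from regulation in podocytes. Of the mesangial and pericyte markers only 2 were above the background range in knockout, Pdgfrb and Sfrp2, and 2 rose. Since 0 were above it in wildtype, any marker above it in knockout had to have the higher mean there. The markers are also too few to decide whether mesangial or pericyte cells, or podocytes with such genes, are the source. A change in podocytes lacking Nck stays open, untested against a difference between lines or in array quality that runs with genotype.

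The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Every division but the real one mixes the genotypes unevenly. It keeps part of the genotype difference and puts the rest into the spread within groups. Counts from such divisions do not show what arrays without a genotype difference would give, so no conclusion is drawn from them. For changed genes 1 of 10 divisions, the real one, reached 3667, and the highest other was 0 in limma, with 159 to 1768 genes at an unadjusted p under 0.05. For genes changed at least 2-fold 1 of 10 reached 515, and the highest other was 0. For shifted lists 2 of 10 reached 12, the other placing wildtype arrays 1 and 3 with knockout array 2 and calling 14.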
